A study of Mus musculus with 15 samples.

How the data were processed

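The series holds 15 one-colour (Cy3) Agilent mouse arrays of RAW264.7 cells in 5 groups of 3 replicates, with groups taken from the sample titles. Per the file headers, the authors scanned the arrays with Feature Extraction 10.7.3.1 under protocol GE1_107_Sep09, on an array design that names genome build mm9. The deposited scanner files give, per spot, a processed signal intensity, which is background-subtracted and spatially and multiplicatively detrended within 1 array, with a surrogate value for spots that are not above background, per the file headers. They also hold the raw mean signal intensity and the local background intensity. The deposited value table holds log2 values that share nearly 1 distribution across arrays (medians 5.80 to 5.83) and correlate with the log2 processed signal at 0.987 to 0.994. The submitters' processing notes name limma without a version. The value table serves as an alternative alone, with 0 of its columns left unused.

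Each array has 62976 spots, of which 3671 controls were left out. The remaining 59305 spots hold 56605 probes, 300 of them in 10 spots each. Spots marked by the scanner software as outliers of uniformity or population were set to missing, the other spots of a probe were averaged, and the log2 processed signal minus the array's 75th percentile was used. A probe was tested when its spot was well above background on at least 2 of the 3 arrays of at least 1 group (28508 probes). A gene is represented by its tested probe with the highest mean, which gave 19506 genes, and 1891 of their values were missing. Of the genes, 6268 have several tested probes. Among these, 389 genes with DEX, 168 with FF, 208 with VSG158 and 203 with VSG159 had probes called in both directions against vehicle, so a gene's value speaks for 1 probe. For 287 named calls against vehicle the genes had 393 other tested probes, of which 303 were called the same way, 65 had the same sign without a call and 25 the opposite sign, 7 of them called. For 97 named calls against DEX these counts were 47, 71, 31 and 0 of 149. Some of these probes were not above background in either group, and the comparison was made after the values were seen. Gene names are those of the files, updated to the reference table's symbols for 347 of the 13445 tested genes found there (GRCm38.p6, used for names alone).

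The 75th percentile of the processed signal was 695 to 1223 per array, 39.6% to 50.4% of noncontrol spots were well above background, and no spot was saturated. Spike-in slopes were 0.910 to 1.02, and spots of a probe varied by 2.02% to 6.31%. Arrays of a group correlated at 0.963 to 0.991. Non-uniform spots numbered 889 on VSG158 replicate 3, 541 on VSG159 replicate 1 and 559 on VSG159 replicate 2, and 26 to 218 on the other arrays.

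All 15 arrays were fitted together with limma 3.58.1 in R 4.3.3 (tables were read with the data.table package, version 1.17.8), with group as the only term and empirical Bayes variances (residual degrees of freedom 10, prior 1.64). The 10 contrasts between groups were tested two-sided, Benjamini-Hochberg adjusted within each contrast, and called under 0.05. An F test compared the 5 groups. A rank or permutation test of 3 arrays against 3 cannot give an exact p below 0.1, which is why single genes were tested with limma. Where a gene's signal was not above background in 1 group, the change is given as "at least N-fold": the brighter group's mean over the mean, per array, of the higher of the lowest signal well above background and the probe's own signal.

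Gene lists, 37 in number, were fixed before the data were examined, as were the groups, contrasts, filter, scaling, alternatives and the genes to be named. Of these lists 34 had at least 5 measured members and were tested with camera at a preset correlation of 0.01, which compares a list with all other genes. Lists of fibroblast, epithelial and neutrophil or mast cell genes had 3, 2 and 4 measured members and were not tested. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance without comparing them with other genes, were run beside it. List counts give members called over all genes and, beside them, members called when adjusted over the list alone. List means and their 95% confidence intervals come from the mean over members per array, and the list medians in comparisons of settings are medians of member changes.

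The named genes are the 12 largest rises and 12 largest falls per comparison with vehicle, and 5 of each between compounds, among called genes whose arrays did not overlap between the groups, with predicted and clone names skipped, and 20 key genes fixed beforehand. Up to 4 examples per list were taken by smallest adjusted p. The single-gene results of 1 gene, 3 in number, are not reported here, and the gene stays in all fits and lists. Chance puts all 3 arrays of 1 group on the same side of all 3 of the other for 10% of genes. In DEX against vehicle, 4427 called genes were higher and 4407 lower with no overlap. The examples printed from these sets, and genes outside them (Serpinb2, Cd86, Cd274, Plk1, Cdc6, F3 and Srm between compounds), were chosen after their values were seen.

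The chance agreement of comparisons that share the vehicle arrays was simulated 100 times with no effects. The procedure was tested on simulated data with known changes for DEX against vehicle over 19506 genes. It recovered 14 of 67 genes (20.9%) with a log2 change of 0.5, 39 of 67 (58.2%) with 1 and 50 of 66 (75.8%) with 2, with median ratios of estimated to true change of 1.11, 1.04 and 1.00. All 45 changes above 10 standard errors were recovered, 6 unchanged genes were called (5.50% of the called), and 0 in simulated VSG158 against FF, which had no change. The 1 shifted list was called and 0 of 33 others were, and the F test over 5 groups called 100 genes with those 67, 67 and 66 changed. No correlation between genes was tested here, while real lists had estimates up to 0.485. The false gene and list calls above may thus be too few for correlated genes. Criteria of 90% and then 80% recovery at the largest change were not met. After that was seen, recovery of the changes above 10 standard errors replaced them.

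Alternatives were quantile normalization, normexp background correction with an offset of 50 followed by quantile or 75th percentile scaling, median scaling, the deposited value table, no filter on dim probes, only probes above background on all 15 arrays, the mean over a gene's tested probes, outlier spots kept, slide as a fixed block (meant where the kind of block is not named) or a random block, each slide alone, replicate number as a block, the 6 arrays of a comparison alone, array quality weights, trended and robust variances, a minimum 2-fold change, and each array left out in turn. A further 3 settings were added after the data were seen: array position as a covariate, slide and position together, and the 3 arrays with the most non-uniform spots left out. With slide as a random block, another form of the list test was used, so its p-values mix a change of test with the block. In VSG158 against vehicle, both on slide 1, the type I interferon median was -1.44 with and without it. The list test's adjusted p was 1.47e-19 without it and 4.56e-45 with it. Explanations for patterns were tested with exact permutations within groups and with other splits of the arrays.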

Results

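Gene expression was measured with one-colour Agilent arrays in RAW264.7 cells, a mouse macrophage-like cell line. The 15 samples form 5 groups of 3 replicates, namely vehicle (labels EtOH and DMSO), dexamethasone (DEX), fluticasone furoate (FF) and 2 compounds known here only by the codes VSG158 and VSG159. DEX and FF are synthetic glucocorticoids. Each steroid was given at 100 nM for 1 h before 1 ug per ml of LPS, a bacterial cell wall component that activates macrophages, for 16 h. The protocol attached to all samples includes LPS, yet the vehicle labels name only the solvents, so the comparisons with vehicle assume that vehicle cells received LPS too. The labels do not say which compound was dissolved in which solvent, so a solvent effect may enter every comparison. The series text calls each treatment duplicated, while the labels give 3 replicates per group. On each array, 39.6% to 50.4% of the noncontrol spots were well above background, and 19506 genes were tested. The number of arrays limits the precision, and the p-values measure spread between samples that may be technical replicates.

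The arrays lay on 2 slides. The first held the 3 vehicle arrays, the 3 VSG158 arrays and VSG159 replicates 1 and 2. The second held VSG159 replicate 3, the 3 FF arrays and the 3 DEX arrays. DEX and FF therefore share no slide with vehicle or VSG158. Each group also fills its own positions. On slide 1 these are 1 to 3 for vehicle, 4 to 6 for VSG158 and 7 and 8 for VSG159. On slide 2 they are 1 for VSG159, 2 to 4 for FF and 5 to 7 for DEX. Within groups, the arrays also varied with their place on the slide, which in all groups but VSG159 rises with replicate number. The first component of their deviations from the group means (35.3% of the variance) correlated with position at r = 0.912 (Spearman 0.918, permutation p = 0.00129 and 0.000514, 15 arrays), at 0.769 within slide 1 (permutation p = 0.0833) and at 0.883 within slide 2 (permutation p = 0.111).

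**Figure D1:**
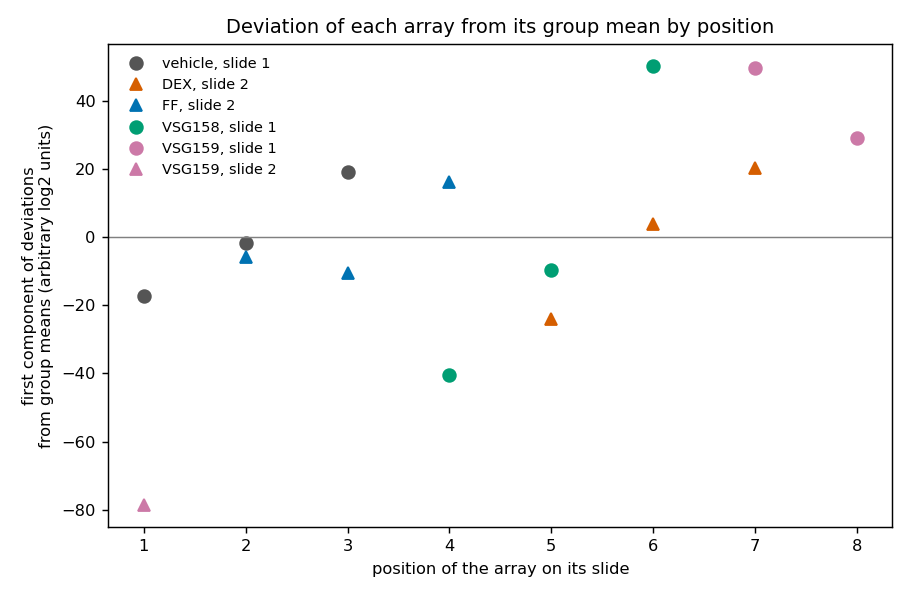
First component of each array's deviation from its group mean (vertical, arbitrary units) by position on the slide (horizontal), coloured by group, with circles for slide 1 and triangles for slide 2. The correlation is 0.912 over the 15 arrays.

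DEX against vehicle shows what a reference glucocorticoid did in these cells. With DEX, the acute-phase gene Hp rose by 5.94 log2 units (SE 0.19, n = 3 arrays per group), the thymidine kinase gene Tk1 by 3.97 (SE 0.12) and the glucocorticoid receptor target Fkbp5 by 3.50 (SE 0.13). The interferon-induced genes Ifit2 and Rsad2 changed by -5.29 (SE 0.16) and -5.35 (SE 0.27). Among inflammatory genes, Cxcl10 changed by -3.04 (SE 0.21), Il1b by -2.06 (SE 0.15), Ptgs2 by -1.52 (SE 0.21), Nos2 by -1.45 (SE 0.12) and Il6 by -1.01 (SE 0.12). For every one of these genes, the 3 DEX arrays lay on 1 side of the 3 vehicle arrays. Changes of genes dim in 1 group are lower bounds: Arl14epl was at least 117-fold, Serpina3g at least 31.9-fold and Batf3 at least 12.8-fold higher, and Tnc was at least 36.9-fold, Krt23 at least 14.1-fold, Arg1 at least 13-fold and Ifnb1 at least 6.64-fold lower.

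Other glucocorticoid-response genes moved less with DEX. Tsc22d3 rose by 0.83 (SE 0.11) on its brightest probe and by 0.24 on another (adjusted p = 0.127, not called), and Klf9 by 0.55 (SE 0.11), the latter with 0.28 and adjusted p = 0.238 when slide was a fixed block and 0.42 and adjusted p = 0.0455 when it was a random one. Dusp1 differed by 0.12 (adjusted p = 0.469) and Per1 by -0.06 (adjusted p = 0.798), neither called. Zfp36, an mRNA decay gene, fell by 0.68 (SE 0.15), with -0.51 and adjusted p = 0.17 under the fixed and -0.59 and adjusted p = 0.0485 under the random block. Mmp9 rose by 0.89 (SE 0.092), and Ccl2 and Acod1 changed by -0.48 (SE 0.11) and -0.51 (SE 0.10). Ifit1 fell by 3.16 (SE 0.13), Il10 fell by 1.35 (SE 0.098) and the mannose receptor gene Mrc1, above background on 2 of 3 DEX arrays, fell by 2.85 (SE 0.18). Tnf changed by -0.31 (SE 0.12, adjusted p = 0.0499), a call lost without any 1 of vehicle 1 or 2, VSG158 1, VSG159 1, 2 or 3, FF 1 or 3 or DEX 1, 2 or 3 (adjusted p 0.0521 to 0.173) and with slide as a fixed (-0.38, adjusted p = 0.172) or random block (-0.34, adjusted p = 0.118). Nr3c1, the glucocorticoid receptor gene, changed by -1.48 (adjusted p = 3.24e-06) on a second probe. On its brightest probe it changed by -0.34 (SE 0.13, adjusted p = 0.0461), a call lost without any 1 of the vehicle arrays, VSG159 1 or 2, the FF arrays or DEX 2 or 3 (adjusted p 0.0533 to 0.147), and its sign turned (0.27) with slide and array position in the model.

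In the type I interferon list, 32 of 36 measured members fell with DEX and 4 were not called (33 fell when adjusted over the list alone), with a mean change of -1.76 (95% CI -1.88 to -1.64, camera adjusted p = 2.2e-18). Examples were Ifit2, Cmpk2 (-5.26), Mx1 (-4.21) and Ifit3 (-3.59). Of 19 interferon gamma and GTPase genes, 18 fell (19 adjusted over the list alone), among them Gbp2 (-3.09), Gbp3 (-2.74) and Irf1 (-2.11). These 2 lists stayed called with an estimated correlation (adjusted p = 0.0286 for each). Proinflammatory cytokine genes fell in 16 of 19 cases and 3 were not called (17 fell adjusted over the list alone), including Il33 (-3.81) and Il15 (-3.12), with a mean of -1.66 (95% CI -1.97 to -1.36) and adjusted p = 0.128 with an estimated correlation. The cell cycle list went up: 33 of 39 members rose, 1 fell and 5 were not called (36 rose and 1 fell adjusted over the list alone), with a mean of 1.45 (95% CI 1.25 to 1.65) and adjusted p = 0.134 with an estimated correlation. Examples are Tk1, Rrm2 (3.60), Mcm6 (2.40) and Mcm2 (2.10). With slide as a block, the medians of the type I interferon, proinflammatory and cell cycle lists were -1.36, -1.85 and 1.37, beside -1.24, -1.38 and 1.43 without it. That block ties DEX to vehicle through VSG159, whose replicate 3 alone lies on slide 2. This array lay farthest from its group mean on the first component (-78.6). In the cholesterol and fatty acid synthesis list 14 of 27 members rose, 3 fell and 10 were not called (14 and 4 adjusted over the list alone; mean 0.39, adjusted p = 0.0241, 0.437 with an estimated correlation, and 0.111 and 0.0379 with slide as a fixed and a random block, where the medians were 0.20 and 0.31 beside 0.45). The list of glucocorticoid-induced genes split, with 8 of 33 members rising, 11 falling and 14 not called (9 and 12 adjusted over the list alone). Its mean was 0.18, while its median (-0.02) and its test (adjusted p = 0.717) pointed down.

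In all, limma called 9037 genes with DEX, 4526 higher (50.1%) and 4511 lower than vehicle, and 48.7% to 49.7% were higher under 5 other scalings. At least 2-fold changes made up 3361 of them. Slide as a block gave 8246 genes, 6053 of them shared, and no slide holds both groups. Scaling each array to its median left 4926 genes, and slide and array position together left 38. Group, slide and position overlap in that model, and some changes turned sign, such as that of Dek (-0.58, then 1.03). By camera, 14 of 34 lists were called, 2 with an estimated correlation, and 8 with slide as a block.

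FF against vehicle asks the same of a second glucocorticoid. With FF, Hp rose by 7.11 (SE 0.19, n = 3 arrays per group), Tk1 by 4.74 (SE 0.12), the polyamine gene Srm by 3.80 (SE 0.12) and Fkbp5 by 3.50 (SE 0.13). Rsad2 changed by -6.59 (SE 0.27), Ifit2 by -6.12 (SE 0.16), Ccl12 by -4.91 (SE 0.12), Cxcl10 by -4.38 (SE 0.21) and Il1b by -3.72 (SE 0.15). Nos2 changed by -2.55, Ptgs2 by -2.42, Il6 by -2.26, Il10 by -2.14 and Zfp36 by -1.41. Arl14epl was at least 95-fold, Serpina3g at least 71.8-fold and the mitotic kinase gene Pbk at least 27.3-fold higher, and Tnc was at least 45.2-fold, Krt23 at least 17.2-fold and Ifnb1 at least 8.13-fold lower. Ifit1 changed by -3.36, Mrc1 by -3.52 (2 of 3 FF arrays above background), Nr3c1 by -0.55 (-1.19 on a second probe), Ccl2 by -0.64 and Acod1 by -0.67, while Mmp9 rose by 0.84. Per1 differed by -0.27 (adjusted p = 0.277, not called). Calls that ended with slide as a fixed block were those of Tsc22d3 (0.45, and 0.32 on a second probe; then 0.32 with adjusted p = 0.23), Klf9 (0.56, then 0.30 with adjusted p = 0.223), Dusp1 (-0.57, then -0.32 with adjusted p = 0.287) and Tnf (-0.46, then -0.54 with adjusted p = 0.0694). A random block kept the calls of Klf9 (0.43, adjusted p = 0.0445) and Tnf (-0.50, adjusted p = 0.0358) and ended the other 2 (adjusted p = 0.0789 and 0.0796).

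Of 36 type I interferon genes, 34 fell with FF (35 adjusted over the list alone; mean -2.07, 95% CI -2.19 to -1.95), and of 19 interferon gamma and GTPase genes 18 fell (19 adjusted over the list alone; mean -1.80), with adjusted p = 0.0195 for both with an estimated correlation. Proinflammatory cytokine genes fell in 18 of 19 cases, also when adjusted over the list alone, with a mean of -2.35 (95% CI -2.66 to -2.05, camera adjusted p = 7.68e-12, and 0.049 with an estimated correlation). In the cell cycle list, 36 of 39 members rose, 1 fell and 2 were not called (37 rose adjusted over the list alone; mean 2.03, 95% CI 1.84 to 2.23, adjusted p = 0.049 with an estimated correlation). The cholesterol and fatty acid synthesis list was also called up: 17 of 27 members rose, 3 fell and 7 were not called, also adjusted over the list alone, among them Fasn (2.26), Scd1 (1.62) and Acaca (1.15), with adjusted p = 0.22 with an estimated correlation. Among MAPK phosphatase and mRNA decay genes, 11 of 17 fell and 6 were not called (12 fell adjusted over the list alone), including Dusp10 (-3.71) and Dusp14 (-2.65), with adjusted p = 0.049 with an estimated correlation. Of 33 glucocorticoid-induced genes, 11 rose, 14 fell and 8 were not called, also adjusted over the list alone, and the mean (0.11) and median (-0.12) differ in sign (adjusted p = 0.524). With slide as a block the medians of the type I interferon, proinflammatory and cell cycle lists were -1.61, -2.38 and 1.98, beside -1.50, -2.01 and 2.03. That block again ties FF to vehicle through VSG159 replicate 3.

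In FF, limma called 8238 genes, 4070 higher (49.4%) and 4168 lower than vehicle, 3236 of them at least 2-fold. The balance turned to 55.7% higher with median scaling, 53.9% in the deposited value table and 53.3% and 53.0% with quantile normalization without and after another background correction. Slide as a block gave 7359 genes, 5428 of them shared, and no slide holds both groups. Median scaling left 4716 genes, and slide and position together left 1070. By camera 21 of 34 lists were called, and 7 with an estimated correlation.

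**Figure D2:**
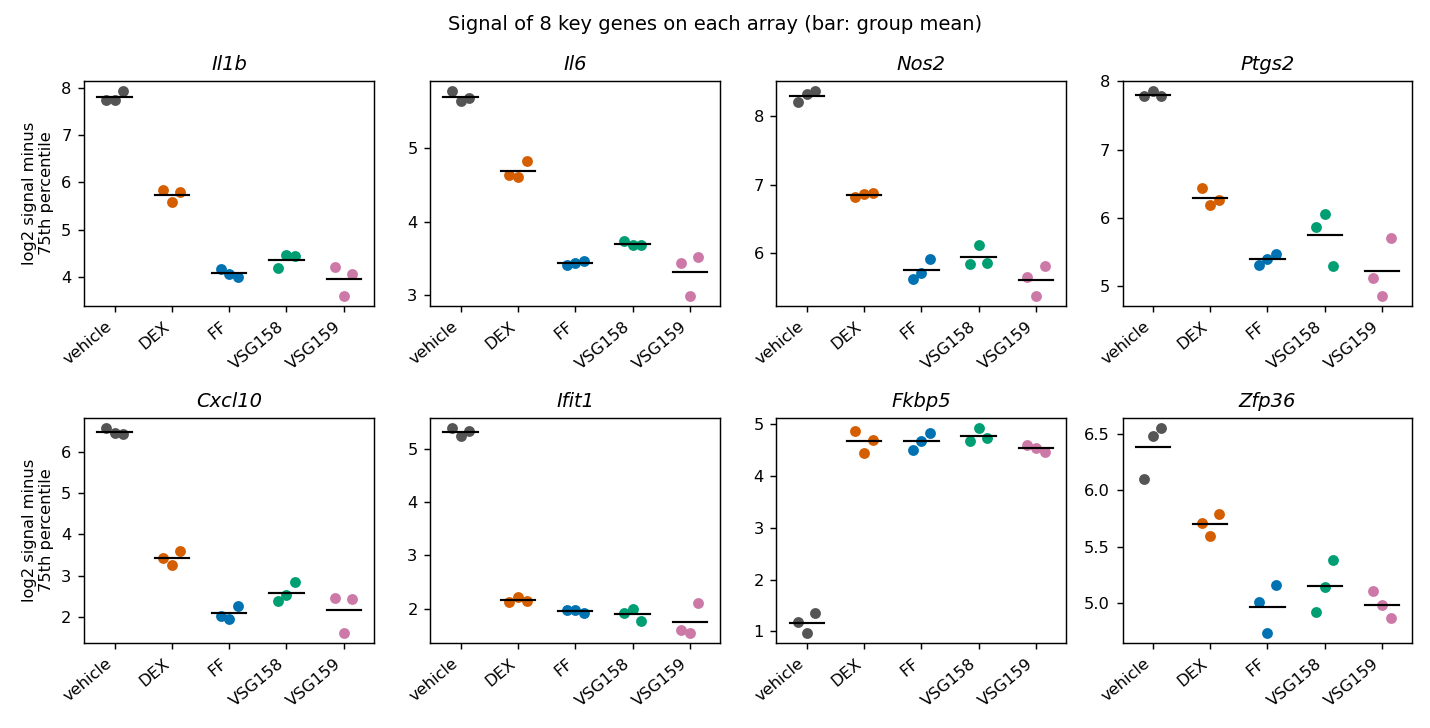
Signal of 8 genes in each of the 15 arrays (log2 processed signal minus the array's 75th percentile), 1 point per array and a bar at each group mean. Il1b fell by 2.06 with DEX and by 3.72 with FF, while Fkbp5 rose by 3.50 with each.

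VSG158 against vehicle asks what the first coded compound did, and both groups lie on slide 1, at positions 4 to 6 and 1 to 3. Hp rose by 7.16 (SE 0.19, n = 3 arrays per group), Tk1 by 4.68 (SE 0.12), Rrm2 by 4.30 (SE 0.17) and Fkbp5 by 3.60 (SE 0.13). Rsad2 changed by -6.01 (SE 0.27), Ifit2 by -5.82, Ccl12 by -4.95 (SE 0.12), Cxcl10 by -3.88 (SE 0.21), Ifit1 by -3.43 and Il1b by -3.43 (SE 0.15). Nos2 changed by -2.36, Ptgs2 by -2.07, Il6 by -2.00, Il10 by -1.95, Zfp36 by -1.23, Tnf by -0.65, Ccl2 by -0.67, Acod1 by -0.71 and Nr3c1 by -0.52 (-0.79 on a second probe). Mrc1 was called lower and was above background on 1 of 3 VSG158 arrays, which leaves the size of its fall unclear. Klf9 rose by 0.61, Tsc22d3 by 0.58 (0.27 on a second probe, adjusted p = 0.0921) and Mmp9 by 0.55, and Per1 differed by -0.31 (adjusted p = 0.207, not called). Dusp1 changed by -0.37 (adjusted p = 0.0394), a call lost within slide 1 alone (adjusted p = 0.0762) and without any 1 of vehicle 3, VSG158 1 or 3, VSG159 2 or the FF arrays (adjusted p 0.0504 to 0.158). Arl14epl was at least 94.1-fold, Serpina3g at least 61.5-fold and Pbk at least 22.8-fold higher, and Tnc was at least 32.1-fold, Krt23 at least 12.2-fold and Arg1 at least 11.3-fold lower.

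Of 36 type I interferon genes 34 fell with VSG158 (35 adjusted over the list alone; mean -2.02, 95% CI -2.14 to -1.9), and of 19 interferon gamma and GTPase genes 18 fell, also adjusted over the list alone (mean -1.86), with adjusted p = 0.0244 for both with an estimated correlation. Of 19 proinflammatory cytokine genes 18 fell, also adjusted over the list alone (mean -2.24, 95% CI -2.55 to -1.94), and of 10 anti-inflammatory mediators 9 fell, also adjusted over the list alone, among them Il18bp (-1.99) and Il10ra (-1.20). Cell cycle genes rose in 36 of 39 cases and 1 fell (37 rose adjusted over the list alone; mean 1.92, 95% CI 1.73 to 2.12). The last 3 lists had adjusted p = 0.0672, 0.055 and 0.0672 with an estimated correlation. In cholesterol and fatty acid synthesis, 15 of 27 genes rose, 3 fell and 9 were not called (17 and 5 adjusted over the list alone; adjusted p = 0.267 with an estimated correlation). Of 33 glucocorticoid-induced genes, 12 rose, 14 fell and 7 were not called, also adjusted over the list alone, and the mean (0.12) and median (-0.03) differ in sign (adjusted p = 0.794).

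With VSG158, limma called 8624 genes, 3848 higher and 4776 lower, 3305 of them at least 2-fold. Slide as a block gave 9261, 8581 of them shared, and slide 1 alone 7958. Median scaling left 4994 genes and shifted the median of all genes to -0.12, beside -0.06. By camera 17 of 34 lists were called, and 2 with an estimated correlation.

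VSG159 against vehicle asks the same of the other coded compound, with replicate 3 on another slide than vehicle. Hp rose by 6.99 (SE 0.19, n = 3 arrays per group), Tk1 by 4.63 (SE 0.12), Rrm2 by 4.37 and Fkbp5 by 3.37 (SE 0.13). Rsad2 changed by -6.40 (SE 0.27), Ifit2 by -6.10, Ccl12 by -5.12 (SE 0.12), Cxcl10 by -4.29 (SE 0.21), Il1b by -3.84 (SE 0.15), Mrc1 by -3.71 (2 of 3 VSG159 arrays above background) and Ifit1 by -3.57. Nos2 changed by -2.69, Ptgs2 by -2.58, Il6 by -2.38, Il10 by -2.09, Zfp36 by -1.39, Tnf by -0.63, Acod1 by -0.53, Ccl2 by -0.50 and Nr3c1 by -0.49 (-1.11 on a second probe). Mmp9 rose by 0.58 and Tsc22d3 by 0.55 (0.08 on a second probe, adjusted p = 0.626), and Per1 differed by -0.28 (adjusted p = 0.245, not called). Within slide 1 alone the calls of Klf9 (0.47, then 0.38 with adjusted p = 0.0627; 0.39 with adjusted p = 0.131 on a second probe) and Dusp1 (-0.50, then -0.42 with adjusted p = 0.0683) ended. Arl14epl was at least 77.0-fold, Serpina3g at least 59.8-fold and Pbk at least 24.1-fold higher, and Tnc was at least 53.0-fold, Krt23 at least 20.2-fold, Arg1 at least 18.7-fold and Ifnb1 at least 9.53-fold lower.

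Of 36 type I interferon genes 34 fell with VSG159, also adjusted over the list alone (mean -2.09, 95% CI -2.21 to -1.97), and of 19 interferon gamma and GTPase genes 18 fell, also adjusted over the list alone (mean -1.86), with adjusted p = 0.0261 for both with an estimated correlation. Of 19 proinflammatory cytokine genes 18 fell, also adjusted over the list alone (mean -2.46, 95% CI -2.77 to -2.16, adjusted p = 0.0644 with an estimated correlation), and of 10 anti-inflammatory mediators 9 fell, also adjusted over the list alone (mean -1.24, adjusted p = 0.0439 with an estimated correlation). Cell cycle genes rose in 35 of 39 cases, 1 fell and 3 were not called (37 rose adjusted over the list alone; mean 1.98, 95% CI 1.78 to 2.17, adjusted p = 0.0644 with an estimated correlation). In cholesterol and fatty acid synthesis 16 of 27 genes rose, 4 fell and 7 were not called (16 and 6 adjusted over the list alone; adjusted p = 0.272 with an estimated correlation). Of 33 glucocorticoid-induced genes, 12 rose, 14 fell and 7 were not called (12 and 15 adjusted over the list alone), and the mean (0.06) and median (-0.27) differ in sign (adjusted p = 0.618). Within slide 1 and with slide as a block, the medians of the type I interferon, proinflammatory and cell cycle lists were -1.50, -2.36 and 2.01, beside -1.49, -2.24 and 2.02. Both settings compare VSG159 1 and 2 with vehicle, so they give the same values and are not 2 separate checks.

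With VSG159, limma called 8595 genes, 3723 higher (43.3%) and 4872 lower, 3341 of them at least 2-fold. Slide as a block gave 10163, 8060 of them shared, and slide 1 alone 8736. Median scaling left 4753 genes, 51.8% of them higher, slide and position together left 2827, and scaling to the 75th percentile after another background correction shifted the median of all genes to -0.13, beside -0.06. By camera 20 of 34 lists were called, and 3 with an estimated correlation.

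**Figure D3:**
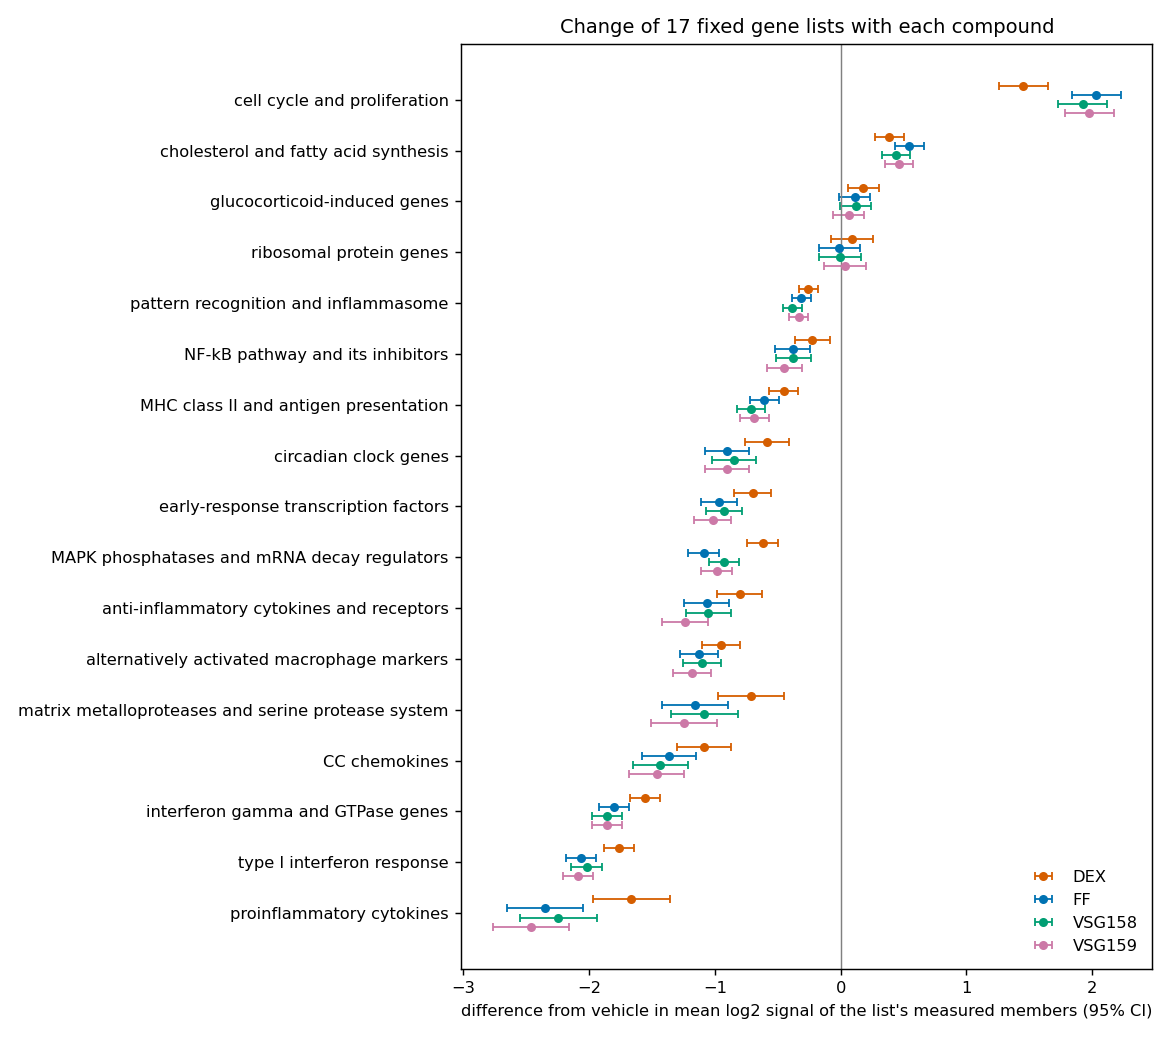
Difference from vehicle in the mean log2 signal of the measured members of 17 gene lists, with 95% confidence intervals, for the 4 compounds. The cell cycle list lies at 1.45 for DEX and between 1.92 and 2.03 for the other compounds, and the proinflammatory list at -1.66 for DEX and between -2.24 and -2.46 for the other compounds.

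The 4 compounds shared much of their change against vehicle. Genes such as Hp, Tk1 and Fkbp5 were among 3047 called higher with all 4 compounds, and Rsad2, Ifit2 and Il1b among 3085 called lower with all 4. The log2 changes of FF and VSG158 correlated at r = 0.894 across genes, those of DEX and FF at 0.847, and the median of the 6 pairs was 0.873 over 19498 genes, which are not independent replicates. All 4 comparisons use the same vehicle arrays. Simulated data with no effects gave r of 0.497 to 0.499 from the shared controls alone, and the covariances of 0.716 to 0.763 exceeded the simulated 0.069 by 0.647 to 0.693. For DEX and FF, 3447 genes were higher with both and 3320 lower with both, beside 944.75 and 964.08 for independent lists. For VSG158 and VSG159 these counts were 3355 and 4127, beside 734.75 and 1193.1. The 3 vehicle arrays cannot be split so that each part keeps a pair, so part of the excess over these values may come from the shared controls. The F test over the 5 groups called 8798 genes (45.1%), and 10265 with slide as a block.

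FF against DEX compares 2 known glucocorticoids on 1 slide, slide 2, where FF holds positions 2 to 4 and DEX 5 to 7. Il1b was lower with FF by -1.66 (SE 0.15, adjusted p = 0.000886, n = 3 arrays per group), Il1a by -1.64 (adjusted p = 0.00227), Serpinb2 by -1.35, Il6 by -1.25 (SE 0.12), Nos2 by -1.10 (SE 0.12), Ccl12 by -1.04 and Cd274 by -1.02. The mitotic kinase gene Plk1 was higher by 1.04 (SE 0.13), the replication gene Cdc6 by 1.03, Srm by 0.93 and the histone gene H2ac4 by 1.48 (SE 0.17). Cxcl10 was lower by -1.34 (adjusted p = 0.00803) and Il10 by -0.80. Each of these calls held when any 1 array was left out. Fkbp5 differed by 0.00 (95% CI -0.29 to 0.30), Tnf by -0.16 and Ccl2 by -0.16, none called, and a p that misses the threshold does not show that the compounds act alike.

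Other key genes were less stable between FF and DEX. Ptgs2 was lower by -0.90 (adjusted p = 0.0418), a call lost without any 1 of the vehicle arrays, VSG158 1, VSG159 1, the FF arrays or the DEX arrays (adjusted p 0.052 to 0.138). Zfp36 was lower by -0.73 (adjusted p = 0.0277), lost without FF 1 or 2 or DEX 1 or 3 (0.0852 to 0.117), and Dusp1 by -0.70 (adjusted p = 0.019), lost without FF 1, 2 or 3 or DEX 1 or 3 (0.0545 to 0.0887). Tsc22d3 differed by -0.39 (adjusted p = 0.0708) and was called without DEX 2 (adjusted p = 0.0386).

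In the cell cycle list 20 of 39 genes were higher with FF than with DEX, none was lower and 19 were not called (30 and 1 adjusted over the list alone; mean 0.58, 95% CI 0.385 to 0.777). Of 19 proinflammatory cytokine genes 7 were lower (10 lower and 1 higher adjusted over the list alone; mean -0.69, 95% CI -0.992 to -0.383), of 36 type I interferon genes 7 were lower (13 and 1 adjusted over the list alone; mean -0.30), and of 17 MAPK phosphatase and mRNA decay genes 7 were lower (9 and 1 adjusted over the list alone). With an estimated correlation these 4 lists had adjusted p = 0.127, 0.127, 0.138 and 0.127.

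Between FF and DEX, limma called 807 genes, 362 higher (44.9%) and 445 lower, 124 of them at least 2-fold. Of the lower genes 238 were below vehicle with both compounds, and of the higher genes 207 were above vehicle with both. The share of higher genes was 60.0% with quantile normalization, 59.2% with quantile normalization after another background correction, 58.6% in the deposited value table and 0 of 2 genes with median scaling. Slide 2 alone gave 688 genes and slide as a block 1522, whereas 131 were called without DEX 3, 192 without DEX 1, 188 without FF 1, 139 without FF 2, 217 without FF 3 and 1402 without VSG159 3. Both groups lie on slide 2, so the block does not correct their difference (cell cycle median 0.69 with and without it). It takes up the deviation of VSG159 3, much as leaving that array out does, and is no separate check. Slide and position together left 0 calls by limma, with 2142 genes at an unadjusted p under 0.05. By camera 18 of 34 lists were called, 0 with an estimated correlation, and 24 by fry.

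VSG158 against DEX has no slide with both groups. Il1a was lower with VSG158 by -1.63 (adjusted p = 0.00212, n = 3 arrays per group), Il1b by -1.37 (SE 0.15, adjusted p = 0.00212), Serpinb2 by -1.10, Ccl12 by -1.08, Il6 by -0.99 (SE 0.12), Cd86 by -0.92 and Nos2 by -0.91. Cdc6 was higher by 0.93 and Plk1 by 0.87. These calls held when any 1 array was left out. Il10 was lower by -0.61, a call lost without DEX 3 (adjusted p = 0.0655). Cxcl10 differed by -0.84 (adjusted p = 0.0662) and was called without VSG159 2 (adjusted p = 0.0156), and Fkbp5 (0.11, 95% CI -0.19 to 0.40), Ptgs2 (-0.55), Zfp36 (-0.55), Dusp1 (-0.49), Tnf (-0.35) and Ccl2 (-0.19) were not called.

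In the cell cycle list 11 of 39 genes were higher with VSG158 than with DEX and 28 were not called (26 higher and 1 lower adjusted over the list alone; mean 0.47, 95% CI 0.276 to 0.669). Among 19 proinflammatory cytokine genes 6 were lower (10 adjusted over the list alone; mean -0.58, 95% CI -0.885 to -0.276), and of 36 type I interferon genes 5 were lower and 1 was higher (15 and 1 adjusted over the list alone; mean -0.26). Each had adjusted p = 0.124 with an estimated correlation. With slide as a fixed block the medians were 0.56 (adjusted p = 2.53e-05), -0.27 (adjusted p = 0.167) and -0.07 (adjusted p = 0.266), so the calls of the last 2 lists ended. A random block, with its other form of the list test, kept these 2 calls (-0.31, adjusted p = 1.73e-05, and -0.17, adjusted p = 0.00281). With slide and position the type I interferon median turned to 0.051.

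Between VSG158 and DEX, limma called 388 genes, 206 higher (53.1%) and 182 lower, 91 of them at least 2-fold. Quantile normalization gave 65.0% higher and median scaling 42.9% of 14 genes, with a median of all genes at -0.11, beside -0.07. Slide as a fixed block gave 929 genes, slide as a random block 0 by limma (2985 at an unadjusted p under 0.05), and without 1 array 84 (DEX 3), 140 (DEX 1), 153 (VSG158 2) and 212 (VSG158 1). The 6 arrays of the comparison alone left 0 genes by limma (2640 at an unadjusted p under 0.05), and slide and position together 0 (574). By camera 15 of 34 lists were called, 0 with an estimated correlation, 25 by fry and 1 with slide as a fixed block.

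VSG159 against DEX shares slide 2 through VSG159 replicate 3 alone. Il1a was lower with VSG159 by -1.96 (adjusted p = 0.000393, n = 3 arrays per group), F3 by -1.93, Il1b by -1.78 (SE 0.15, adjusted p = 0.000328), Il6 by -1.38 (SE 0.12), Serpinb2 by -1.35, Nos2 by -1.24 and Cd86 by -0.97. Plk1 was higher by 0.93 and Cdc6 by 0.86. These calls held when any 1 array was left out. Cxcl10 was lower by -1.25 (adjusted p = 0.00864) and Il10 by -0.74. Calls were lost without VSG159 1 or 2 or DEX 1 or 3 for Ptgs2 (-1.07; 0.0574 to 0.0844), and without VSG159 2 or DEX 1 or 3 for Zfp36 (-0.71; 0.0817 to 0.106) and Dusp1 (-0.62; 0.0624 to 0.103). Fkbp5 (-0.13, 95% CI -0.43 to 0.16), Tsc22d3 (-0.28), Tnf (-0.33) and Ccl2 (-0.02) were not called.

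In the cell cycle list 19 of 39 genes were higher with VSG159 than with DEX, 1 was lower and 19 were not called (29 and 2 adjusted over the list alone; mean 0.53, 95% CI 0.329 to 0.722). Among 19 proinflammatory cytokine genes 8 were lower (14 lower and 1 higher adjusted over the list alone; mean -0.80, 95% CI -1.1 to -0.493), of 36 type I interferon genes 12 were lower and 1 higher (21 and 1 adjusted over the list alone; mean -0.33), and of 17 MAPK phosphatase and mRNA decay genes 8 were lower (10 and 1 adjusted over the list alone). With an estimated correlation these lists had adjusted p = 0.109, 0.109, 0.138 and 0.109. Within slide 2, where VSG159 has replicate 3 alone, the medians of the first 3 lists were 0.57, -0.36 and -0.20, beside 0.61, -0.51 and -0.31 over all arrays. Slide as a block gave the same values, since it compares that same array with DEX, and is no second check. Of 33 glucocorticoid-induced genes 7 were lower with VSG159 than with DEX and 26 were not called (9 lower and 1 higher adjusted over the list alone; list adjusted p = 0.21).

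Between VSG159 and DEX, limma called 1082 genes, 281 higher (26.0%) and 801 lower, 150 of them at least 2-fold, and 36.0% were higher with quantile normalization after another background correction. Slide as a block gave 666 genes, with VSG159 replicate 3 as the only VSG159 array on the slide of DEX. The count for slide 2 alone is not weighed here, as VSG159 has 1 array there. Without 1 array the count was 194 (VSG159 2), 209 (DEX 3), 267 (DEX 1), 507 (VSG159 1), 658 (FF 3) and 713 (FF 2). Median scaling left 30 genes, the 6 arrays of the comparison alone 0 by limma (3341 at an unadjusted p under 0.05), and slide and position together 0 (773). By camera 17 of 34 lists were called, 0 with an estimated correlation, 27 by fry, and 9 with slide as a block. Across the 3 comparisons with DEX, 129 genes were higher and 125 lower with all 3 compounds, against the same 3 DEX arrays.

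**Figure D4:**
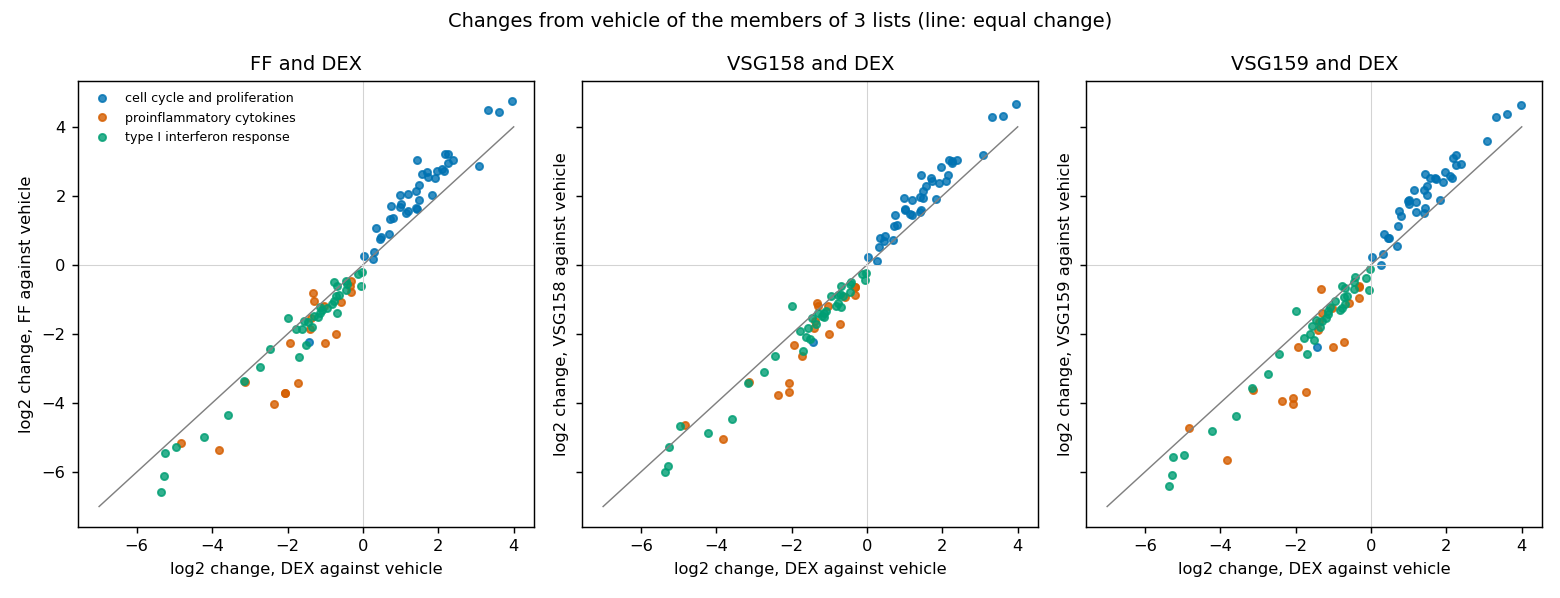
Log2 change against vehicle of the members of 3 gene lists with DEX (horizontal) and with FF, VSG158 or VSG159 (vertical, 1 panel each), with a line at equal change. The mean of the cell cycle list was higher than with DEX by 0.58, 0.47 and 0.53, and that of the proinflammatory list differed by -0.69, -0.58 and -0.80.

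VSG158 against FF compares a coded compound with a known one, with no shared slide. No gene was called by limma, with 1229 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.356. Il1b differed by 0.28 (95% CI -0.039 to 0.61, n = 3 arrays per group), Cxcl10 by 0.50 (95% CI 0.049 to 0.96), Nos2 by 0.19 (95% CI -0.083 to 0.46) and Fkbp5 by 0.10 (95% CI -0.19 to 0.40). Camera called 2 lists up, the chemokine receptors (mean 0.41) and the MAPK phosphatase and mRNA decay genes (mean 0.16, 95% CI 0.0388 to 0.284), each with adjusted p = 0.0022 and 0.276 with an estimated correlation, and 0 of their members were called over all genes (2 and 1 adjusted over the list alone). The median of the receptor list turned from 0.39 to -0.20 with slide as a block, where 0 lists were called. The cell cycle list differed by -0.11 (95% CI -0.305 to 0.088), the proinflammatory list by 0.11 (95% CI -0.198 to 0.411; median 0.01, but 0.44 with adjusted p = 0.0511 under a fixed and 0.26 with adjusted p = 0.0103, a call, under a random slide block) and the type I interferon list by 0.05 (95% CI -0.0736 to 0.168). Without VSG158 1, 29 genes were called, and with slide as a block 0, while 1 list was called without VSG158 3 and 4 without VSG158 2. Median scaling moved the median of all genes to -0.14, beside -0.03.

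VSG159 against FF called no gene by limma, with 1177 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.233. Il1b differed by -0.12 (95% CI -0.45 to 0.20, n = 3 arrays per group), Il6 by -0.13 (95% CI -0.39 to 0.14) and Fkbp5 by -0.13 (95% CI -0.43 to 0.16). The cell cycle list differed by -0.06 (95% CI -0.252 to 0.141), the proinflammatory list by -0.11 (95% CI -0.415 to 0.195) and the type I interferon list by -0.02 (95% CI -0.144 to 0.098), and 0 of 34 lists were called by camera or fry. Without VSG159 3 the count was 96 genes, without DEX 2 it was 1, with slide as a block 1 and with array quality weights 2490. Slide 2 holds 1 VSG159 array, so no count is given there.

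VSG158 against VSG159 compares the coded compounds with each other. No gene was called by limma, with 1203 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.803. Il1b differed by 0.41 (95% CI 0.085 to 0.73, n = 3 arrays per group), Il6 by 0.39 (95% CI 0.12 to 0.65), Ptgs2 by 0.52 (95% CI 0.048 to 0.98) and Nos2 by 0.33 (95% CI 0.055 to 0.60), each with adjusted p = 0.803. Camera called the proinflammatory cytokine list (mean 0.22, 95% CI -0.0881 to 0.521) and the prostaglandin list (mean 0.19) up, with adjusted p = 0.0282 and 0.642 with an estimated correlation, and 0 of their members were called over all genes. The lists called were 0 without VSG158 1 or VSG159 2, 1 without VSG158 3 or VSG159 3 and 6 without VSG159 1. The proinflammatory list median was 0.19, and 0.24 (adjusted p = 0.0401) within slide 1. The cell cycle list differed by -0.05 (95% CI -0.249 to 0.143) and the type I interferon list by 0.07 (95% CI -0.0508 to 0.191). Slide 1 alone gave 0 genes and slide as a block 34, and 35 were called without VSG158 1 and 34 without VSG159 3, with a median of all genes at -0.11 under median scaling, beside 0.03. Over these 3 comparisons the distance from estimate to bound of the 95% interval of a gene's difference had a median near 0.38, and genes without a call may still differ.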

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

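All tests of single explanations in this part were chosen after the result was seen, while the counts over other splits of the arrays were planned.

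In 18 comparisons a gene was called in opposite directions against vehicle with DEX and with another compound. The difference between the compounds was called in each, which this choice of genes nearly ensures. Cxcl3, a neutrophil-attracting chemokine gene, was 0.50 above vehicle with DEX (adjusted p = 0.0333) and changed by -0.98 with FF, -0.92 with VSG158 and -1.66 with VSG159, so that these differed from DEX by -1.49, -1.42 and -2.16. The DEX call of Cxcl3 was lost without vehicle 2 or 3 or DEX 1 or 3 (adjusted p 0.0677 to 0.119), and with slide as a fixed block (0.20, adjusted p = 0.622). Dek, a chromatin gene, changed by -0.58 with DEX and by 0.60, 0.76 and 0.64 with FF, VSG158 and VSG159, with differences of 1.18, 1.34 and 1.22. Slide as a fixed block ended its DEX and FF calls with changes of similar size (-0.53 and 0.64, adjusted p = 0.137 and 0.0854), slide and position together turned its DEX change to 1.03, and on a second probe of Dek the DEX change was 0.02 (adjusted p = 0.948). Zfp36l2, an mRNA decay gene, changed by 0.53 with DEX, -0.45 with FF and -0.56 with VSG159, with differences of -0.97 and -1.08, and its FF call against vehicle was lost without vehicle 3 or FF 2 or 3 (adjusted p 0.0604 to 0.0777). Rsrc1 changed by -0.24 with DEX, 0.38 with VSG158 and 0.37 with VSG159, with differences of 0.61 and 0.61. On a second probe its DEX and VSG159 changes were not called (adjusted p = 0.18 and 0.719), and its DEX call was lost without any 1 of vehicle 1 or 3, VSG158 2, VSG159 1 or 2, the FF arrays or DEX 1 or 3 (adjusted p 0.0523 to 0.153).

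The other 8 genes were called in 1 pair each. Haspin changed by -0.49 with DEX and 0.49 with FF (0.017 with slide as a fixed block, adjusted p = 0.97), a difference of 0.98, lost without any 1 of FF 1, 2 or 3 or DEX 1 or 3 (adjusted p 0.0507 to 0.0805). Acin1 changed by -0.79 with DEX and 0.38 with VSG158, a difference of 1.17, and its VSG158 call was lost without any 1 of the vehicle arrays, VSG158 2 or 3, VSG159 2, the FF arrays or DEX 1 (adjusted p 0.0546 to 0.164). Cep295 changed by -0.44 with DEX and 0.42 with VSG158, a difference of 0.86, and Zfp157 by -0.37 and 0.37, a difference of 0.74. Both differences were lost without VSG158 1 or 2 or DEX 1 or 3 (adjusted p 0.0508 to 0.0882), and the mean over probes gave 0.77 for Cep295 and 0.091 for Zfp157 with DEX, the opposite sign. Klhl35 changed by 0.60 with DEX and -0.57 with VSG158, a difference of -1.17, lost without DEX 1 or 3 (adjusted p 0.0532 to 0.0736). Tor2a changed by 0.22 with DEX and -0.21 with VSG159, a difference of -0.43, lost without VSG159 2 or DEX 3 (adjusted p = 0.0565). 4930430F21Rik and Gm41148 changed by 1.85 and 2.73 with DEX and by -2.56 and -2.46 with VSG159, with differences of -4.42 and -5.19, but their VSG159 values rest on 1 array, the other 2 having outlier spots, and turned positive (0.71 and 1.13) when these were kept. Leaving out 1 array also ended calls against vehicle of Haspin, Cep295, Zfp157, Klhl35 and Tor2a, with adjusted p from 0.0503 to 0.154. Slide as a fixed block ended the DEX calls of Zfp36l2 (0.33), Rsrc1 (-0.28), Acin1 (-0.48), Cep295 (-0.60), Zfp157 (-0.51) and Tor2a (0.21; adjusted p 0.102 to 0.306), the FF call of Zfp36l2 (-0.65, adjusted p = 0.0595) and the VSG159 call of Tor2a (-0.22, adjusted p = 0.0544). The changes of Zfp36l2 and Acin1 with DEX shrank and the others kept their size or grew, so most of these losses came without a smaller change, and DEX and FF share no slide with vehicle. Slide and position together turned the DEX changes of Haspin (0.12), Cep295 (0.37) and Tor2a (-0.098).

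DEX stood apart from the other compounds at more genes than these did from each other, with 388, 1082 and 807 genes called against VSG158, VSG159 and FF and 0 in the 3 other pairs. Not every setting kept this: array quality weights gave 2490 genes between VSG159 and FF, beside 966 between VSG158 and DEX, and median scaling left 14, 30 and 2 against DEX. A difference between slides as the whole cause is argued against by slide 2 alone, where 688 genes were called between FF and DEX, while VSG158 against FF, on different slides, gave 0. A position term left the DEX differences at a median ratio of 0.999 to those without it, 0.972 to 1.01 leaving out 1 array. This ratio cannot decide on a trend with position. VSG158 (positions 4 to 6) and DEX (5 to 7) nearly share their positions, so the term could move that difference little. The ratio was not taken for FF (2 to 4) alone, and its genes were those called without the term. Slide and position together, which lowered the DEX differences to 0.80 of their size (0.699 to 0.862 without 1 array) and raised their standard errors 1.47 to 3.30 times, cannot be told apart from the compound, because the model could not be fitted without VSG159 3, the only array that ties the slides within a group. A biological difference stays open as a hypothesis. An action of DEX at 100 nM that is weaker on part of the genes may account for it, and no other dose was measured. An equally weaker action on all genes is at odds with major-axis slopes against DEX of 0.993 (FF), 0.978 (VSG158) and 1.03 (VSG159) over all genes. The shared vehicle arrays enter both axes and pull these slopes towards 1, and DEX lies on another slide than vehicle, so they are weak evidence.

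In these 3 comparisons 10 splits of 6 arrays are too few for a share under 0.05. The real splits called 388 (VSG158), 1082 (VSG159) and 807 (FF) genes against DEX, and the highest other splits 7, 27 and 1, with 1 of 10 splits reaching the real count in each case.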

How the results depend on the processing

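Position as a covariate, slide and position together, and leaving out the 3 arrays with the most non-uniform spots were chosen after the result was seen, the other settings before. Most named results held. A result held when it kept its call and direction, or when it was called in neither the main fit nor the other setting, whatever its sign. Of 1185 named gene results, 1106 held with quantile normalization, 1060 with normexp and quantile normalization and 880 with median scaling (305 lost their call). Without the filter on dim probes 996 held, with slide as a fixed block 1017 (145 lost, 23 gained) and with slide and position together 670 (496 lost). Of 340 list results, 228 held with an estimated correlation in camera (112 lost), 295 with slide as a fixed block and 337 with the replicate block. The comparisons with DEX depend most on the setting, and for genes near the background the signal over background limits the fold, which is then a lower bound. Except where a reason is given, the cause was not tested.

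Requiring a 2-fold change as well gave, by construction, fewer genes: 3361 (DEX), 3236 (FF), 3305 (VSG158) and 3341 (VSG159) against vehicle, and 91 (VSG158), 150 (VSG159) and 124 (FF) against DEX. Camera with an estimated correlation called 2, 7, 2 and 3 lists against vehicle in the order DEX, FF, VSG158 and VSG159, and 0 in each comparison between compounds. Fry, which asks another question, called 28, 31, 29 and 31 against vehicle, 25, 27 and 24 against DEX in the order VSG158, VSG159 and FF, and 0 between VSG158 and FF and between VSG158 and VSG159.

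Against DEX, again in the order VSG158, VSG159 and FF, quantile normalization gave 670 genes for VSG159, normexp with quantile normalization 251, 430 and 476, the authors' deposited log2 values 233, 371 and 377, no filter on dim probes 78, 159 and 111, the mean over probes 683 for VSG159, and only probes above background on all 15 arrays 1248 for FF. Median scaling gave 4926, 4716, 4994 and 4753 against vehicle, 14, 30 and 2 against DEX, and 3991 by F test. The lists called between VSG158 and FF and between VSG158 and VSG159 were 0 and 0 with normexp and quantile normalization, 1 and 0 with normexp and the 75th percentile, 1 and 1 with median scaling, 0 and 0 in the value table, 8 and 5 without the filter, 1 (VSG158 against FF) on probes above background everywhere and 4 (VSG158 against FF) with the mean over probes. Without the filter 22 lists were called for DEX and 26 for VSG158 against vehicle, and the median correlation of effects was 0.774.

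Slide as a fixed block gave 929, 666 and 1522 genes against DEX, 1 between VSG159 and FF and 34 between VSG158 and VSG159. The lists called were 8 (DEX against vehicle), 1 (VSG158 against DEX), 9 (VSG159 against DEX), 0 (VSG158 against FF) and 1 (VSG158 against VSG159). Slide as a random block (correlation 0.420) gave 0 genes by limma (2985 at an unadjusted p under 0.05) between VSG158 and DEX and 221 between VSG159 and DEX. Slide 1 alone gave 1 list between VSG158 and VSG159, with fewer arrays. Slide 2 alone gave 196 genes and 8 lists between VSG159 and DEX. VSG159 has 1 array there, so these counts cannot test the difference, and no conclusion is drawn from them. Replicate numbers share only a number across groups: over 30 pairs of arrays with the same number, deviations from group means correlated at -0.06 on average (-0.53 to 0.28; 0.069 over the 18 pairs without VSG159), and 3 of 15 arrays correlated best with their own number. With replicate number as a block (replicate block), 223, 484 and 309 genes were called against DEX. Using the 6 arrays of a comparison alone left 0 and 0 genes by limma for VSG158 and VSG159 against DEX (2640 and 3341 at an unadjusted p under 0.05), and 0 lists between VSG158 and VSG159, with fewer residual degrees of freedom. Array quality weights gave 966, 3574 and 3784 genes against DEX, 2490 between VSG159 and FF, and 1 and 0 lists for VSG158 against FF and against VSG159.

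Position as a covariate gave 740 (VSG158) and 2163 (VSG159) genes against DEX. Slide and position together, which share much with the groups, gave 38 (DEX), 1070 (FF) and 2827 (VSG159) genes against vehicle, 0, 0 and 0 by limma against DEX (574, 773 and 2142 at an unadjusted p under 0.05), 5 between VSG159 and FF, and 1 (VSG158 against DEX), 7 (VSG159 against DEX), 1 (VSG159 against FF) and 1 (VSG158 against VSG159) lists. Without the 3 arrays with the most non-uniform spots, 685 (VSG158) and 2171 (FF) genes were called against DEX, the lists were 9 (VSG159 against DEX), 1 (VSG158 against FF) and 1 (VSG158 against VSG159), and the correlation of effects was 0.826.

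Leaving out 1 array in turn, where a group of 2 remains, gave 7531 to 9886 (DEX), 7116 to 8847 (FF), 7404 to 9261 (VSG158) and 7290 to 10148 (VSG159) genes against vehicle, 84 to 572 (VSG158), 194 to 1574 (VSG159) and 131 to 1402 (FF) against DEX, 0 to 29 between VSG158 and FF, 0 to 96 between VSG159 and FF, 0 to 35 between VSG158 and VSG159, and 7021 to 10737 by F test. The lowest counts against DEX came without DEX 3 (84 and 131) and VSG159 2 (194), and the highest without VSG159 3. The lists called were 11 to 16 (DEX), 19 to 22 (FF), 16 to 19 (VSG158) and 15 to 22 (VSG159) against vehicle, and 11 to 19, 16 to 18 and 17 to 19 against DEX. They were 1 to 4 between VSG158 and FF, 0 between VSG159 and FF, and 0 to 6 between VSG158 and VSG159. The correlation of effects was 0.841 to 0.882.

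Among named results called in the main fit or in the other setting, directions turned in few. Sign changes of results called in neither are not listed. An example is the chemokine receptor median with DEX against vehicle, -0.62 and then 0.07 with slide as a fixed block. In FF against DEX, Mctp2 was -0.11 and Fcgr3 0.059 with normexp and quantile normalization, Mctp2 -0.19 with normexp and the 75th percentile, and Mctp2 -0.15 and Fcgr3 0.052 in the value table. With the mean over probes, which mixes probes that disagree, H2-T23 was 0.73, 0.55, 0.16 and 0.81 against vehicle (DEX, FF, VSG158 and VSG159), and with DEX Rps4x was -0.0030, Cep295 0.77 and Zfp157 0.091. In the same setting Cep295 was -0.18 in VSG158 against DEX, Errfi1 0.76, Tlr3 0.26, Plin2 0.073 and Txnrd1 0.45 in VSG159 against DEX, Pla2g4a 0.048 in FF against DEX, and the NF-kB list -0.028 in FF against DEX by its median, with its test pointing up. With outlier spots kept, 4930430F21Rik was 0.71 and Gm41148 1.13 in VSG159 against vehicle. With slide and position, DEX against vehicle gave Nr3c1 0.27, Laptm5 0.42, Rpl13 -0.097, Rps4x -0.64, Pax5 0.22, Lck -0.15, Dek 1.03, Haspin 0.12, Cep295 0.37 and Tor2a -0.098, and FF against vehicle Rpl13 -0.075 and Pax5 0.073. VSG158 against DEX gave Trim30a -0.057, Ifi205 0.068, Nfkb2 0.048, Dusp4 0.14, Laptm5 -0.30, Bhlhe40 0.036, and the type I interferon list 0.051, the glycolysis list 0.0067 and the cholesterol list -0.069, and VSG159 against DEX gave Irgm1 0.021. Slide as a fixed block turned the chemokine receptor list to -0.20 in VSG158 against FF. Fry pointed the other way than camera for the nitric oxide list with DEX (median -0.28) and the oxidative stress list with FF (0.083) and VSG159 (-0.049).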

Other observations

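The tests of position and brightness within groups, and those of slide and scaling for the cell cycle genes, were chosen after the result was seen. The test of position for the cell cycle genes and the counts over other splits were planned.

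Other gene groups moved against vehicle in all 4 compounds, given here in the order DEX, FF, VSG158 and VSG159. Of 19 early-response transcription factors 10, 14, 13 and 14 fell (11, 14, 14 and 14 adjusted over the list alone), among them Atf3 (-2.25, -3.01, -2.87 and -3.05) and Ier3 (-1.38, -2.06, -1.88 and -2.33), with list adjusted p = 0.00164, 0.000102, 0.00044 and 0.000239. Of 10 CC chemokine genes 8, 7, 7 and 7 fell, also adjusted over the list alone, with Ccl7 at -1.90, -3.00, -2.76 and -2.84, while 1, Ccl6 (0.70), rose with DEX. Of 10 genes of antigen presentation 6, 8, 7 and 7 fell (7, 8, 7 and 7 adjusted over the list alone), with Tap1 at -1.25 to -1.51. Of 14 circadian clock genes 8, 8, 8 and 7 fell and 1 rose in each (8, 8, 8 and 9 fell adjusted over the list alone), with Bhlhe40 at -1.64 to -2.63. Of 17 markers of alternatively activated macrophages 10, 9, 9 and 9 fell, also adjusted over the list alone, and of 21 adhesion and costimulatory genes 10, 13, 12 and 13 fell (10, 13, 15 and 13 adjusted over the list alone), with Cd83 at -2.49 to -3.25. Of 23 genes of the NF-kB pathway and its inhibitors 9, 13, 12 and 14 fell (9, 13, 12 and 15 adjusted over the list alone), with Tnip3, an inhibitor of the pathway, at -1.13 to -1.50. Camera called these lists down in all 4 comparisons, and with an estimated correlation only the antigen presentation list with FF kept its call (adjusted p = 0.049), the others having adjusted p from 0.054 to 0.439. The anti-inflammatory list (7 of 10 fell with DEX and with FF; 7 and 8 adjusted over the list alone) and the MAPK phosphatase list (10, 10 and 12 of 17 fell with DEX, VSG158 and VSG159, also adjusted over the list alone) were called down too, with adjusted p = 0.101 and 0.166 for DEX, and for the second list 0.0924 and 0.072 for VSG158 and VSG159, with an estimated correlation. The first list had 0.049 with FF there. With slide as a fixed block the DEX calls of these 2 lists and of the adhesion, antigen presentation and circadian lists were lost (adjusted p 0.0606 to 0.111), with medians of -0.84, -0.55, -0.58, -0.32 and -0.75, beside -0.54, -0.43, -0.29, -0.47 and -0.59. A random block, with its other form of the list test, kept these 5 calls (adjusted p 0.00287 to 0.0428) and ended that of the NF-kB list with DEX (0.0606).

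Further lists were called in some comparisons. The metalloprotease and serine protease list (9, 9, 10 and 11 of 16 fell, and 9, 10, 10 and 11 adjusted over the list alone), macrophage identity genes (10, 15, 14 and 13 of 24 fell, and 10, 15, 15 and 13 adjusted over the list alone) and lipid uptake genes (13 of 21 fell and 5 rose in each, also adjusted over the list alone, Fabp4 by 2.64 to 2.87) were not called with DEX (adjusted p = 0.067, 0.0711 and 0.0711), and the last not with VSG159 either (adjusted p = 0.0558). CXC chemokines, chemokine receptors, glycolysis and the unfolded protein list were called with FF and VSG159 (adjusted p = 0.0349, 0.0156, 0.0402 and 0.0402 with FF) and not with DEX or VSG158, and all 8 calls were lost with slide as a fixed block (adjusted p 0.0603 to 0.375). Their medians kept about their size or grew, except that the chemokine receptor median with FF went from -1.26 to -0.26. They were -1.28, -0.38 and -0.27 for the 3 other lists with FF (beside -0.98, -0.31 and -0.23), and -1.19, -0.99, -0.32 and -0.23 with VSG159 (beside -1.11, -1.05, -0.28 and -0.16). A random block, with its other form of the list test, kept the CXC chemokine, chemokine receptor and unfolded protein calls (adjusted p 0.0043 to 0.0141). It called these lists with VSG158 too (0.0127 to 0.0232) and ended the glycolysis calls (0.0929 and 0.0818). The chemokine receptor median with VSG158 was -0.86 with and without this block (adjusted p = 0.0232 and 0.0835), so that call came without a change in size. The fixed block also ended those of the macrophage identity list with FF and VSG159 (medians -0.56 and -0.54, beside -0.41 and -0.55; adjusted p = 0.0859 and 0.0907) and of the lipid uptake list with FF and VSG158 (-0.77 and -0.74, as without it; adjusted p = 0.0998 and 0.0542), and so did the random block (adjusted p 0.0561 to 0.138). None of these 7 lists kept a call with an estimated correlation (adjusted p = 0.0954 at the lowest). The random block called the pattern recognition list with all 4 compounds (adjusted p 0.0112 to 0.049), the unfolded protein list with DEX (0.049) and the apoptosis list with VSG159 (0.0417). Lists that were called in no comparison with vehicle without a slide block split between rises and falls. Nitric oxide genes had 4 rises and 7 falls of 12 with DEX, prostaglandin genes 6 and 5 of 14, pattern recognition genes 6 and 13 of 32, phagocytosis genes 6 and 14 of 28, osteoclast genes 3 and 9 of 17, apoptosis genes 3 and 7 of 20, metabolic glucocorticoid response genes 5 and 4 of 13 (Angptl4 by 3.19), oxidative stress genes 3 and 3 of 21, receptor and cofactor genes 6 and 4 of 16, complement genes 6 and 6 of 20, ribosomal protein genes 5 and 1 of 29, and markers of B and T cells 1 and 3 of 6. Adjusted over the list alone, these counts were the same but for 7 rises among pattern recognition genes. Adjusted p with DEX ran from 0.0778 to 0.776. The prostaglandin list's mean and median differ in sign with FF (-0.06 and 0.19) and VSG158 (-0.01 and 0.19), and the oxidative stress list's with FF (-0.05 and 0.08) and VSG158 (-0.04 and 0.04), as do the complement list's with FF (-0.14 and 0.04) and VSG158 (-0.07 and 0.06), the ribosomal list's with VSG158 (-0.01 and 0.02) and the receptor and cofactor list's with VSG159 (0.13 and -0.01). The oxidative stress list with VSG159 and the ribosomal list with FF had a test pointing up beside a mean (-0.06 and -0.01) and median (-0.05 and -0.02) below 0.

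Arrays of a group varied with their position on the slide. The first component of the deviations rose with the position number, which counts the arrays row by row and so gives an order, not a distance. Permuting positions within groups gave p = 0.00129 (r = 0.912, 7776 permutations, and 0.00258 adjusted over the 2 measures tested). The correlation was 0.937 without the 2 arrays farthest from the median position and 0.859 without the VSG159 arrays, which lie on both slides. A gradient along the slide was not tested. Brightness of the arrays as the whole cause is argued against, since position kept p = 0.00772 after the relation to brightness was taken out, while brightness had p = 0.106 alone (r = 0.693) and 0.332 after position. In the 4 groups other than VSG159 position and replicate number rise together, and there replicate 1 lies below and replicate 3 above 0 on this component. The 2 can be told apart through VSG159 alone, whose replicate 3 also lies on another slide. Order of handling, which the labels do not give, may follow either and stays open. No biological explanation was tested, because replicates of a group have none in the design.

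Cell cycle genes were higher with all 4 compounds than with vehicle, where DEX gave 1.45 and the others 1.92 to 2.03. With an estimated correlation only the FF call was kept (adjusted p = 0.049, beside 0.134, 0.0672 and 0.0644 for DEX, VSG158 and VSG159). Position alone is argued against for FF and VSG159 by FF 1, FF 2 and VSG159 3, at positions 1 to 3 of slide 2. They were 2.04 above the 3 vehicle arrays at the same positions of slide 1 (SE 0.057, exact p = 0.1, the smallest possible). The other compound arrays were 1.78 above vehicle. Slide alone is argued against for VSG158 and VSG159 by the 5 compound arrays on slide 1. At positions 4 to 8, these were 1.94 above vehicle there (SE 0.0715, exact p = 0.0179), beside 1.78 on slide 2. No DEX array on its own was matched to vehicle in either comparison, and neither speaks to slide and position acting together. The scaling is argued against by a lowest ratio of 0.844 to the reported differences over 5 other scalings. A biological hypothesis is that the compounds may relieve a slowing of proliferation by LPS, which needs vehicle cells without LPS, and none are among the samples. A difference in cell number at harvest stays open too, as no measure of it is among the values.

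Other splits of the 6 arrays were counted for each pair of groups, and 10 splits are too few for a share under 0.05. Against vehicle the real splits called 9037 (DEX), 8238 (FF), 8624 (VSG158) and 8595 (VSG159) genes and the highest other splits 0, 0, 2 and 2, so 1 of 10 splits reached the real count in each. Between FF and VSG158 or VSG159, where the real splits called 0 genes by limma (1229 and 1177 at an unadjusted p under 0.05), the highest other splits called 0 and 2, and all 10 splits reached the real count. Between VSG158 and VSG159 the real split called 0 genes by limma (1203 at an unadjusted p under 0.05), while the split of VSG158 1, VSG158 2 and VSG159 3 against VSG158 3, VSG159 1 and VSG159 2 called 5403, which points to a structure of the samples. The latter 3 arrays hold positions 6 to 8 of slide 1 and had the most non-uniform spots (889, 541 and 559) and the highest 75th percentiles (1223, 1170 and 1220), and slide as a block gave 34 genes for the real split. For the F test over 5 groups, 8798 genes were called in the real split and 25 in the highest other split, with 1 of 100 splits reaching the real count. A random split of the arrays is thus unlikely to give this count. Other splits mix vehicle and compound arrays, which raises their spread within groups and keeps their counts low. The groups also follow slide and position, which these splits cannot separate from the compounds.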
